A study of Rattus norvegicus with 12 samples.

How the data were processed

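RNA was measured in 12 samples of rat hippocampus, each pooled from 3 to 4 animals per the labels, on single-colour Affymetrix-type oligonucleotide arrays, 1 array per sample. The groups were taken from the treatment text of each sample and the replicate numbers from the sample titles. KA is not spelled out in the labels. It is taken here as kainic acid, a glutamate receptor agonist used to induce seizures, because the series is about seizures. PBS is phosphate-buffered saline, the vehicle control.

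The deposited values are probe set signals, that is array intensity on a linear scale, and the summary method is not given in the sources used here. From the values, each array had been scaled so that its mean, after leaving out the lowest and highest 2% of probe sets, was 150. The array medians lay between 70.06 and 74.1, a ratio of 1.058, which is under the limit of 1.25 that had been set for normalizing again, so the deposited intensity was kept as it was. It ran from 0.0036 to 5591 over 15923 probe sets. The number of arrays, not a read depth, limits the precision.

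The 57 control probe sets were left out. Values were put on the scale log2(signal + 17), where 17 is the 20th percentile of the table, so fold changes of dim genes are understated. The 60% of the other 15866 probe sets with the highest mean over all 12 samples were tested, which left 9520, with a lowest mean log2 value of 5.997. Gene names came from the array annotation table supplied with the values. In it 12789 probe sets had 1 gene symbol and 312 had several; 2822 were not listed and are unnamed here. Of those with 1 symbol, 12754 were matched by Entrez ID to a RefSeq gene table, which changed 0 symbols, and 35 kept the symbol of the annotation. A probe set with several symbols was never given a gene name.

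Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 model with a mean per group over all 12 samples, so that the 4 groups of 3 shared an estimate of the spread with 13.1 degrees of freedom. There were 7 contrasts: KA against PBS in isolated rats, in enriched rats and as the mean of both; enriched against isolated after PBS, after KA and as the mean of both; and the interaction, which is the KA effect in enriched rats minus that in isolated rats. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 9520 probe sets of a contrast, with a threshold of 0.05. Standard errors (SE) are those of the limma model unless stated otherwise.

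Gene lists of cell types, pathways and receptor families were written down in advance, 27 in all. For these, 1 probe set per gene was used, the one with the highest mean, which gave 6923 genes. The sex-linked list had 0 genes above the filter, so 26 lists were tested. They were called with limma's camera at a preset correlation of 0.01 between genes. Beside each call stand camera with a correlation estimated from the residuals and the number of members that passed when p-values were adjusted over the list alone. The shift of a list was also tested by an exact permutation test of its score, the mean log2 value of its members in each sample after centring each gene; 3 samples against 3 cannot give a two-sided p below 0.1. These permutation p-values are unadjusted unless given as adjusted over the lists. Here SE between samples means the error of that score, from the spread within the 4 groups.

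The rule for naming genes was also fixed in advance. In a contrast where fewer than 10 genes passed, every passing gene was named, together with the 6 higher and 6 lower genes of smallest unadjusted p, given as values that did not pass. Up to 4 members per list were named by smallest p, and Gfap, Aif1, Bdnf, Npy, Fos, Arc, Ttr and Mbp wherever they were measured. Fos lay below the filter, so only its signal is given. The design, the main settings, the lists, this rule and all alternatives but 1 were chosen before the data were examined.

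The steps were tested on simulated data with the residual spread of these arrays. For KA against PBS in isolated rats, 61.2% of 67 probe sets changed by a log2 of 0.5 were called with the right sign among 9520, 97% of 67 changed by 1 and 98.5% of 66 changed by 2, and 3.39% of the 177 called were false. For the mean housing effect the shares were 94%, 100% and 100%, with 3.45% false of 203. The noise there was independent and the spreads were shuffled across probe sets. These shares hold for that many changed probe sets and need not hold for the real contrasts, where far fewer were called. The microglial list, shifted by a log2 of 0.3 with independent noise, was called (camera, adjusted p = 5.39e-07). In the real data its residual correlation was 0.526, so its power there was not tested. When the residuals were dealt out again with no group effect, keeping the correlation between genes, the preset correlation called at least 1 of the 26 lists in 57 of 100 draws, and the estimated correlation in 0 of 100. Calls at the preset correlation are therefore given with both values.

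Alternatives were quantile normalization, equal array medians, a lower pseudocount of 3 and a higher one of 47, no filter, a stricter filter that kept 40%, an intensity trend with robust variances, array weights, a fit of only the groups compared, the replicate number as a block, 1 probe set per gene, fry in place of camera, and each sample left out in turn. A covariate for RNA quality was added after the data were seen. RNA quality was described by the log2 ratio of the 3 prime to the 5 prime control probe sets of beta-actin, GAPDH and hexokinase. Pairs of contrasts were correlated across probe sets beside 100 simulated draws with no effect. The control probe sets and the probe sets below the filter entered no test.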

Results

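The study profiled gene expression in the hippocampus of young rats to ask whether enriched housing lessens the damage that seizures do to neurons. Rats received KA or PBS at postnatal day 20. Some then lived alone for 10 days until tissue was taken (isolated), and the others were kept in large cages with 8 rats per cage (enriched). There were 4 groups of 3 samples, named here PBS_isolated, KA_isolated, PBS_enriched and KA_enriched. Each sample was a pool of 3 to 4 animals, so n counts pools, and the labels do not say which litter or cage an animal came from. P-values therefore measure the spread between pools, and an effect of a shared cage cannot be told apart from enriched housing. No group had ordinary group housing, so in every housing comparison an effect of enrichment cannot be told apart from one of isolation.

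The 12 arrays were alike in level and pattern. Pearson correlations of log2 values between pairs of arrays lay between 0.9808 and 0.9894 within groups and between 0.9818 and 0.9905 across groups, and no pair held identical values. KA_enriched replicate 3 stood apart. Its mean correlation with the others was the lowest at 0.9830, it lay at 19.05 on a first principal component that held 19.2% of the variance, and its log2 ratios of 3 prime to 5 prime signal were the highest for beta-actin (0.856), GAPDH (0.249) and hexokinase (1.599). The beta-actin ratio averaged 0.470 ± 0.0996 (SD, n = 3) in PBS_isolated, 0.470 ± 0.148 in KA_isolated, 0.550 ± 0.0561 in PBS_enriched and 0.650 ± 0.185 in KA_enriched. Its difference between enriched and isolated rats was 0.130 (SE 0.076; exact permutation p = 0.11).

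In isolated rats, KA-treated hippocampus carried more signal of microglial, macrophage and complement genes than PBS-treated hippocampus. All 18 measured members of the microglia, macrophage and complement list were higher, by a mean log2 of 0.54 (SE between samples 0.18, n = 3 per group), or 1.45-fold. The list rose relative to other genes (camera, adjusted p = 1.14e-20), with adjusted p = 0.135 with an estimated correlation and an exact permutation p = 0.1 for its score (0.371 adjusted over the lists). The SE and the estimated correlation also draw on the enriched samples, which are not part of this comparison. SDs of the score were 0.049 in PBS_isolated and 0.117 in KA_isolated, against 0.299 in PBS_enriched and 0.308 in KA_enriched. Complement component C3 had a signal of 28.7 ± 0.806 (SD, n = 3) in PBS_isolated and 93.4 ± 20.9 in KA_isolated. Cd74, the invariant chain of MHC class II, had 39.1 ± 10.4 and 138 ± 44.0, and the class II gene RT1-Da 33.9 ± 7.38 and 77.8 ± 16.2. The receptor Csf1r, on which microglia depend for survival, had 206 ± 4.20 and 313 ± 36.0, and P2ry12, a purine receptor of resting microglia, 114 ± 16.5 and 170.5 ± 3.79. None of the 18 members passed over all genes tested (0), while 14 passed adjusted over the list alone. Laptm5, a lysosomal membrane protein of leukocytes, was nearest to passing, with a log2 of 0.485 (SE 0.105, adjusted p = 0.589), followed by P2ry12 (0.525, SE 0.14), Cd74 (1.45, SE 0.39) and Lyz2 (0.33, SE 0.093). Aif1 did not move with the list, at 65.6 ± 17.5 and 66.3 ± 9.85, although its other tested probe set gave a log2 of 0.63.

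The high state of these genes was also present in single enriched samples. C3 signal was 24.2, 99.1 and 22.5 in PBS_enriched replicates 1, 2 and 3, and 24.6, 26.4 and 105.9 in KA_enriched replicates 1, 2 and 3. Cd74 followed, with 42.2, 152 and 59.7 in PBS_enriched and 43.9, 33.6 and 123.6 in KA_enriched. Csf1r was 316 in PBS_enriched replicate 2 and 285 in KA_enriched replicate 3, against 182 to 247 in the other 4 enriched samples. Scores of the whole microglial list were -0.022, -0.034 and 0.056 in PBS_isolated, 0.498, 0.666 and 0.443 in KA_isolated, 0.019, 0.551 and 0.048 in PBS_enriched, and 0.081, -0.073 and 0.520 in KA_enriched.

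**Figure D1:**
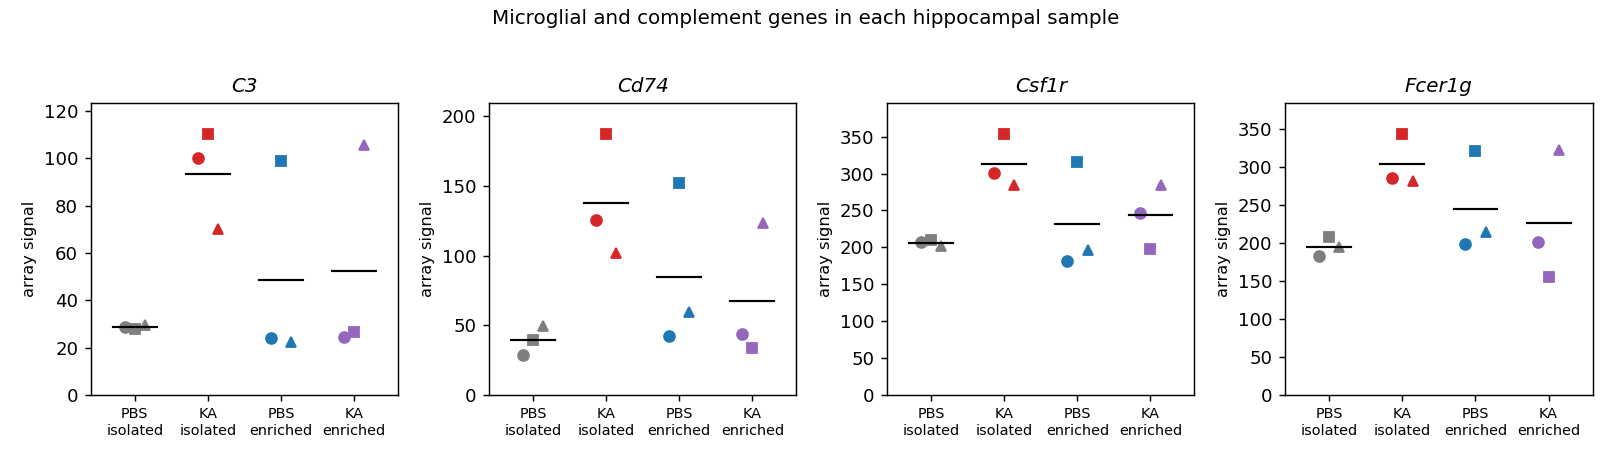
Array signal (linear scale) of C3, Cd74, Csf1r and Fcer1g in each sample; circle, square and triangle are replicates 1, 2 and 3, and the line is the group mean. C3 lay between 69.95 and 110.2 in KA_isolated, at 99.1 in PBS_enriched replicate 2, at 105.9 in KA_enriched replicate 3, and between 22.5 and 29.5 in the other 7 samples.

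Genes of reactive gliosis were higher in KA_isolated too. Of 8 measured members 7 were higher, with a mean log2 of 0.27 (SE between samples 0.089; adjusted p = 2.65e-06, adjusted p = 0.135 with an estimated correlation); 0 passed over all genes and 3 adjusted over the list alone. These were the small heat shock protein gene Hspb1 (log2 0.65, SE 0.16), the protease inhibitor gene A2m (0.37, SE 0.12) and S100a10 (0.24, SE 0.078). The heat shock and oxidative stress list was higher by a mean log2 of 0.079 (SE between samples 0.026; 14 of 20 members; adjusted p = 0.0352, adjusted p = 0.267 with an estimated correlation; 0 passed over all genes and 1, Hspb1, adjusted over the list alone). Voltage-gated ion channel genes were lower in 18 of 21 members, with a mean log2 of -0.094 (SE between samples 0.044; adjusted p = 0.0123, adjusted p = 0.306 with an estimated correlation; 0 passed over all genes and 0 adjusted over the list alone). Its members of smallest p were the potassium channel genes Kcnc1 (-0.375, SE 0.162) and Kcna2 (-0.26, SE 0.13) and the sodium channel gene Scn1a (-0.20, SE 0.11). Tissue and cell type markers separated the same samples without being called. Among 26 lists some separate 3 samples from 3 with no effect (exact permutation p = 0.1 for each). Pyramidal cell markers had a mean log2 of -0.055 (SE between samples 0.029, adjusted p = 0.307), with scores of -0.066 to -0.048 in KA_isolated and -0.021 to 0.019 in PBS_isolated. Thalamus and striatum markers had 0.050 (SE between samples 0.019, adjusted p = 0.34), with scores of 0.024 to 0.068 and -0.012 to 0.006. Without PBS_isolated replicate 1 or 3 or KA_isolated replicate 1 or 2, the heat shock call was lost (lowest mean 0.0684, adjusted p = 0.129), and without PBS_isolated replicate 3 (-0.059, adjusted p = 0.29) or KA_isolated replicate 2 the ion channel call was lost.

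Over single genes, 1 of 9520 probe sets differed between KA and PBS in isolated rats. Anp32a, a nuclear phosphoprotein that inhibits phosphatase 2A, fell by 1.251 on the log2 scale (SE 0.134, adjusted p = 0.00361), from 392 ± 63.9 (SD, n = 3) to 154 ± 18.9, and was lower in all 3 KA samples. At an unadjusted p under 0.05 there were 410 probe sets, 4.31% of those tested. The higher genes of smallest p that did not pass were Maf, Laptm5, Gipc1, Reep6, Serinc2 and Msn, with log2 values from 0.29 to 0.565, and the lower ones were Adissp, Shc2, Htr5b, Hrh3, Mrps11 and Tshz2, from -0.526 to -0.33. Among them are the receptor genes Htr5b for serotonin (log2 -0.45, SE 0.096, adjusted p = 0.589) and Hrh3 for histamine (-0.35, SE 0.076, adjusted p = 0.589). Gfap, the astrocyte intermediate filament, was 1913 ± 200 in PBS_isolated and 2393 ± 300 in KA_isolated (log2 0.32, SE 0.13, adjusted p = 0.999). Bdnf (0.115, SE 0.088), Npy (-0.033, SE 0.087), Arc (-0.35, SE 0.13), Ttr (-1.09, SE 0.93) and Mbp (-0.029, SE 0.084) did not pass either. With only the groups compared in the fit, 5 probe sets passed, 4 of them higher.

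In enriched rats, no gene and no list was called between KA and PBS. The microglial list had a mean log2 of -0.03 (SE between samples 0.18, adjusted p = 0.858) and reactive gliosis genes -0.0090 (SE between samples 0.089, adjusted p = 0.858). The microglial mean balanced a high score in PBS_enriched replicate 2 (0.551) and in KA_enriched replicate 3 (0.520) against -0.073 to 0.081 in the other enriched samples. Its sign depends on which of these high samples is left out. Immediate early genes had 0.053 (SE between samples 0.043, adjusted p = 0.691). limma called 0 of 9520 probe sets, with 474 at an unadjusted p under 0.05, and 0 of 26 lists were called by camera with either correlation or by fry. The lowest adjusted p of a probe set was 0.842. Scores of 3 uncalled lists separated KA_enriched from PBS_enriched. With 3 samples against 3 a full separation has an exact permutation p = 0.1, so among 26 lists such a count may arise with no effect. GABA receptor subunits were lower, with a mean log2 of -0.062 (SE between samples 0.023), and so were thalamus and striatum markers, with -0.055 (SE between samples 0.019). Both overlapped with equal medians, and thalamus and striatum markers also with quantile normalization. Choroid plexus markers were higher, with 0.356 (SE between samples 0.290, adjusted p = 0.23). Genes of smallest p that did not pass were Lfng, Mllt10, Vsir, Plxnb2, Wdr59 and Coa8 on the higher side, with log2 values from 0.26 to 0.49, and Svop, F3, Tpgs1, Decr2, Pdcl3 and Chga on the lower side, from -0.62 to -0.31. The synaptic vesicle gene Svop had 510 ± 16.9 in PBS_enriched and 327 ± 47.9 in KA_enriched (SD, n = 3; log2 -0.62, SE 0.13). Chga, a granin of dense-core vesicles, had 335 ± 11.6 and 249 ± 36.1, and Per1, a clock gene, 34.4 ± 20.3 and 75.1 ± 10.3. Gfap (log2 0.068, SE 0.13), Aif1 (0.30, SE 0.14), Bdnf (-0.086, SE 0.088), Npy (-0.054, SE 0.087), Arc (0.14, SE 0.13), Ttr (0.89, SE 0.93) and Mbp (0.11, SE 0.084) did not pass. Without PBS_enriched replicate 2 or KA_enriched replicate 3, camera called 1 list.

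The KA effect was compared between the housings through the interaction. Microglial genes had a KA effect lower by a mean log2 of 0.57 in enriched than in isolated rats, that is an interaction of -0.57 (SE between samples 0.26), with 17 of 18 members negative. The list was called (adjusted p = 6.23e-11), with adjusted p = 0.368 with an estimated correlation and an exact permutation p = 0.07 for its score (0.364 adjusted over the lists); 0 members passed over all genes and 0 adjusted over the list alone. Reactive gliosis genes had -0.28 (SE between samples 0.125; adjusted p = 0.00175, adjusted p = 0.368 with an estimated correlation; exact permutation p = 0.05, or 0.358 adjusted over the lists), 0 members passing over all genes and 2, Hspb1 and A2m, adjusted over the list alone. Hspb1 was 35.5 ± 11.6 and 64.2 ± 3.53 (SD, n = 3) in PBS_isolated and KA_isolated, and 57.7 ± 11.5 and 52.5 ± 11.3 in PBS_enriched and KA_enriched. Heat shock genes had -0.122 (SE between samples 0.037; adjusted p = 0.0454, adjusted p = 0.368 with an estimated correlation), and choroid plexus markers 0.63 (SE between samples 0.41; adjusted p = 0.0454, adjusted p = 0.436 with an estimated correlation), each with 0 members passing over all genes and 0 adjusted over the list alone. The choroid plexus value rested on the thyroid hormone carrier Ttr in PBS_isolated replicate 1, and without that sample it was 0.27 (adjusted p = 0.409). limma called 0 of 9520 probe sets for the interaction, with 473 at an unadjusted p under 0.05. The named genes of smallest p were Cpsf4, Hrh3, Sstr4, Shc2, Anp32a and Lfng, positive with log2 values from 0.48 to 0.82, and F3, Reep6, Leprot, Gipc1, Svop and Maf, negative with values from -0.73 to -0.41. The somatostatin receptor gene Sstr4 was 70.6 ± 8.70 and 54.0 ± 1.93 in PBS_isolated and KA_isolated, and 54.4 ± 4.09 and 68.5 ± 5.36 in PBS_enriched and KA_enriched (log2 0.56, SE 0.12, adjusted p = 0.758). Gfap (-0.25, SE 0.19), Aif1 (0.275, SE 0.20), Bdnf (-0.20, SE 0.125), Npy (-0.021, SE 0.12), Arc (0.485, SE 0.19), Ttr (1.98, SE 1.31) and Mbp (0.14, SE 0.12) did not pass. The heat shock call was lost without any 1 of 7 samples (weakest -0.0964, adjusted p = 0.281, without KA_enriched replicate 1) and the choroid plexus call without any 1 of 7. Both calls were also lost with no filter and with the replicate number as a block.

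**Figure D2:**
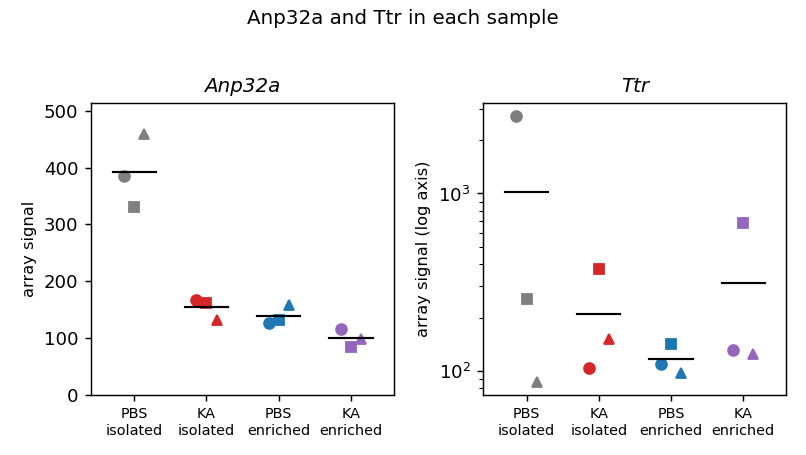
Array signal of Anp32a (linear axis) and Ttr (log axis) in each sample; circle, square and triangle are replicates 1, 2 and 3, and the line is the group mean. Anp32a lay between 331 and 459 in PBS_isolated and between 83.7 and 167.5 in the other 9 samples, and Ttr reached 2719 in PBS_isolated replicate 1 against 87.2 to 683 elsewhere.

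Activity-regulated genes of the hippocampus were higher with enriched housing in the mean of both treatments. Taking PBS and KA rats together, Egr1, a transcription factor induced by neuronal activity, was 1.37-fold higher in enriched rats (log2 0.45, SE 0.065, adjusted p = 0.042). Its signal was 448 ± 29.7 and 398 ± 18.3 (SD, n = 3) in PBS_isolated and KA_isolated, and 584 ± 69.6 and 588 ± 37.3 in PBS_enriched and KA_enriched. The 6 enriched samples, at 540 to 664, all lay above the 6 isolated ones, at 378 to 475. Arc, a synaptic regulator made on demand, was 249 ± 27.6 and 192 ± 8.59 in the isolated groups and 318 ± 32.7 and 356 ± 78.6 in the enriched groups (log2 0.58, SE 0.093, adjusted p = 0.105). The transcription factor Egr4 had a log2 of 0.56 (SE 0.095, adjusted p = 0.112). Neither passed, and for both all 6 enriched samples lay above all 6 isolated ones. The immediate early and activity-regulated list had a mean log2 of 0.16 (SE between samples 0.03), with 16 of 20 members higher (adjusted p = 1.64e-08, adjusted p = 0.0707 with an estimated correlation, exact permutation p = 0.01 for its score, or 0.26 adjusted over the lists). Of its members 1 passed over all genes and 7 adjusted over the list alone: Egr1, Nr4a2, Nr4a3, Nr4a1, Arc, Egr4 and Junb. Junb, an AP-1 component, had a log2 of 0.36 (SE 0.075), and the orphan nuclear receptor genes Nr4a1, Nr4a2 and Nr4a3 had 0.28, 0.33 and 0.24. Per1 was the lowest member (-0.238, SE 0.180). Members near 0 were Sik1 (-0.008), Klf4 (0.021), Dusp5 (0.030), Crem (-0.064), Homer1 (0.018, SE 0.057; 0.437 for another of its probe sets), Jun (0.035, SE 0.047), Rgs2 (0.027, SE 0.055) and Plk2 (-0.065, SE 0.059). Fos, below the filter, had signals of 23.6 to 41.6 in the isolated and 36.7 to 73.6 in the enriched samples.

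**Figure D3:**
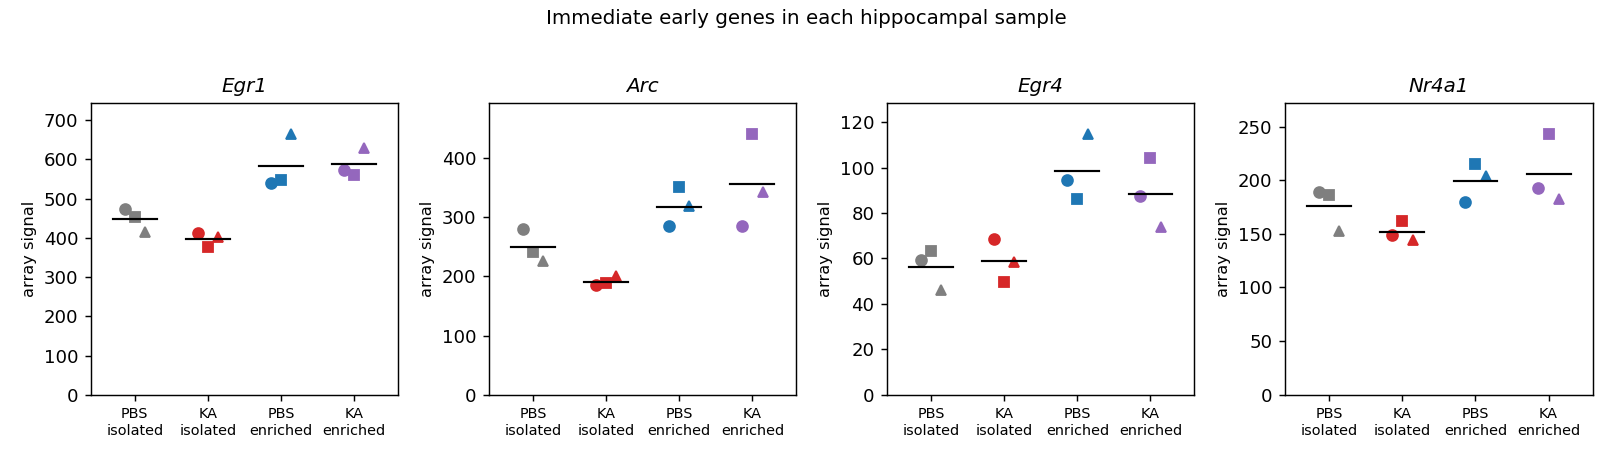
Array signal (linear scale) of Egr1, Arc, Egr4 and Nr4a1 in each sample; circle, square and triangle are replicates 1, 2 and 3, and the line is the group mean. Egr1 lay between 378 and 475 in the 6 isolated samples and between 540 and 664 in the 6 enriched samples.

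The mean housing effect called 2 of 9520 probe sets, Egr1 higher and Anp32a lower (log2 -0.97, SE 0.095, adjusted p = 0.00124), with 537 at an unadjusted p under 0.05. Higher genes of smallest p that did not pass were Arc, Egr4, Rbm14, Xrcc4, Epha5 and Snhg11, with log2 values from 0.24 to 0.58, and lower ones were Ivd, Fxyd6, Pnpt1, Raver1, Zzef1 and Lage3, from -0.302 to -0.23. Xrcc4, of DNA end joining, was 49.2 ± 1.34 and 52.0 ± 0.812 (SD, n = 3) in the isolated groups and 61.6 ± 3.01 and 64.5 ± 3.18 in the enriched groups (log2 0.24, SE 0.047, adjusted p = 0.215). Ivd, a leucine breakdown enzyme, had a log2 of -0.30 (SE 0.056, adjusted p = 0.215). Bdnf, a neurotrophin, was 109 ± 4.37 and 119 ± 3.87 in the isolated and 135 ± 14.9 and 126 ± 12.6 in the enriched groups (log2 0.16, SE 0.062, adjusted p = 0.832). Npy had a log2 of 0.15 (SE 0.061), Gfap -0.14 (SE 0.094), Aif1 0.034 (SE 0.10), Ttr -0.70 (SE 0.66) and Mbp 0.015 (SE 0.059), none passing. The thalamus and striatum list, a sign of neighbouring tissue, had a mean log2 of 0.054 (SE between samples 0.014, adjusted p = 0.442), and the beta-actin ratio of 3 prime to 5 prime signal was higher by 0.130 in enriched rats. The Egr1 call was lost when any 1 of the 12 samples was left out, with a log2 between 0.41 and 0.48 and adjusted p between 0.0552 and 0.209, and without filtering, with equal medians, a lower pseudocount, array weights, the replicate block or the beta-actin covariate.

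Within PBS rats, enriched housing went with lower Anp32a and, less clearly, with higher immediate early genes. Anp32a fell by 1.38 on the log2 scale (SE 0.13, adjusted p = 0.00115), from 392 ± 63.9 to 139 ± 17.0 (SD, n = 3), and was the only 1 of 9520 probe sets called, with 401 at an unadjusted p under 0.05. The immediate early list had a mean log2 of 0.10 (SE between samples 0.043; 12 of 20 members higher; adjusted p = 0.00409, adjusted p = 0.327 with an estimated correlation; exact permutation p = 0.2, or 0.6 adjusted over the lists), with 0 members passing over all genes and 2, Egr1 (0.37, SE 0.092) and Egr4 (0.66, SE 0.13), adjusted over the list alone. Its scores overlapped, at 0.034 to 0.156 in PBS_enriched and -0.059 to 0.056 in PBS_isolated. The heat shock list had 0.099 (SE between samples 0.026; 19 of 20 members; adjusted p = 0.00589, adjusted p = 0.299 with an estimated correlation), led by Hspb1, Cryab and Hspa1a. The microglial list had 0.21 (SE between samples 0.18; adjusted p = 0.00238, adjusted p = 0.623 with an estimated correlation) and reactive gliosis 0.14 (SE between samples 0.089; adjusted p = 0.0372, adjusted p = 0.516 with an estimated correlation). Thalamus and striatum markers had 0.11 (SE between samples 0.019; 7 of 8 members; adjusted p = 0.0357, adjusted p = 0.299 with an estimated correlation), and choroid plexus markers were lower, with -0.48 (SE between samples 0.29; adjusted p = 0.0357, adjusted p = 0.458 with an estimated correlation). In these last 5 lists 0 members passed over all genes and 0 adjusted over the list alone. Genes of smallest p that did not pass were Egr4, Poll, Epha5, Akap17a, Egr1 and Mbtd1, higher, and Ivd, Fxyd6, LOC102555617, Tshz2, Grp and Hrh3, lower; Ivd was nearest, with a log2 of -0.51 (SE 0.080, adjusted p = 0.116). Bdnf (0.265, SE 0.088), Npy (0.16, SE 0.087), Arc (0.33, SE 0.13), Gfap (-0.017, SE 0.13), Aif1 (-0.10, SE 0.14), Ttr (-1.69, SE 0.93) and Mbp (-0.057, SE 0.084) did not pass. Some calls here rested on 1 sample. Without PBS_enriched replicate 2 the microglial mean was 0.034 (camera, adjusted p = 0.773) and reactive gliosis 0.056 (adjusted p = 0.729). Without PBS_isolated replicate 1 choroid plexus was -0.124 (adjusted p = 0.756). The immediate early call was lost without PBS_enriched replicate 2 (0.076, adjusted p = 0.0762) or PBS_isolated replicate 3, and the reactive gliosis call also without PBS_isolated replicate 1 or 3. Other calls were lost while the mean moved little. These were heat shock without PBS_isolated replicate 3 or PBS_enriched replicate 3 (lowest 0.0845) and choroid plexus without PBS_enriched replicate 1 or 2. Thalamus and striatum lost the call without any 1 of 5 samples, with means of 0.101 to 0.111.

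Within KA rats, immediate early genes were higher and microglial genes lower in enriched than in isolated rats. The immediate early list had a mean log2 of 0.22 (SE between samples 0.043; 16 of 20 members; adjusted p = 5.41e-08, adjusted p = 0.0945 with an estimated correlation; exact permutation p = 0.1, or 0.743 adjusted over the lists), with 0 members passing over all genes and 7 adjusted over the list alone. Arc had a log2 of 0.82 (SE 0.13, adjusted p = 0.234) and Egr1 0.54 (SE 0.092, adjusted p = 0.234), neither passing. The microglial list had -0.36 (SE between samples 0.18; 17 of 18 members lower; adjusted p = 3.55e-08, adjusted p = 0.611 with an estimated correlation; exact permutation p = 0.3, or 0.867 adjusted over the lists) and reactive gliosis -0.14 (SE between samples 0.089; 7 of 8 members lower; adjusted p = 0.0368, adjusted p = 0.611 with an estimated correlation), both with 0 members passing over all genes and 0 adjusted over the list alone. KA_enriched replicate 3, whose array stood apart, was high in the microglial list; without it the microglial mean was -0.53. Pyramidal cell markers, not called, had 0.078 (SE between samples 0.029, adjusted p = 0.378), with scores of -0.041 to 0.063 in KA_enriched and -0.066 to -0.048 in KA_isolated that overlapped with equal medians. The beta-actin ratio was higher by 0.180 in KA_enriched (SE 0.107, exact permutation p = 0.3). limma called 0 of 9520 probe sets, with 668 at an unadjusted p under 0.05, 388 of them higher. Higher genes of smallest p after Arc and Egr1 were Rhobtb2, Snhg11, Rbm14 and Synj1, with log2 values from 0.32 to 0.46, and lower ones were Anp32a (-0.56), Fxyd1, Gpr108, Leprot, Bcl2l1 and F3. Gfap (-0.27, SE 0.13), Aif1 (0.17, SE 0.14), Bdnf (0.063, SE 0.088), Npy (0.14, SE 0.087), Ttr (0.29, SE 0.93) and Mbp (0.087, SE 0.084) did not pass. Without KA_enriched replicate 1, Arc passed (log2 0.96, adjusted p = 0.0479). The reactive gliosis call was lost without KA_isolated replicate 2 or 3 or KA_enriched replicate 1 or 2. Its mean was -0.081 without KA_isolated replicate 3 and moved little without KA_isolated replicate 2 or KA_enriched replicate 2. The microglial mean was -0.235 without KA_enriched replicate 2.

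Averaged over both housings, KA went with higher microglial and reactive gliosis genes, a rise that came from isolated rats, with 0.536 and 0.270 there. In enriched rats neither was higher after KA. Mean scores were 0.176 in KA_enriched and 0.206 in PBS_enriched for the microglial list, and 0.132 and 0.141 for reactive gliosis. The microglial list had a mean log2 of 0.25 (SE between samples 0.129; 18 of 18 members higher; adjusted p = 4.53e-11, adjusted p = 0.449 with an estimated correlation; exact permutation p = 0.17, or 0.442 adjusted over the lists) and reactive gliosis 0.13 (SE between samples 0.063; 8 of 8 members; adjusted p = 0.00418, adjusted p = 0.449 with an estimated correlation), both with 0 members passing over all genes and 0 adjusted over the list alone. Without KA_enriched replicate 3 the microglial mean was 0.167. Anp32a was the only 1 of 9520 probe sets called (log2 -0.84, SE 0.095, adjusted p = 0.00647), with 410 at an unadjusted p under 0.05. Genes of smallest p that did not pass were Vsir, Ybx3, Mllt10, Klhl13, Plxnb2 and Kctd6, higher, and Tpgs1, Adissp, Eif2s3, Htr5b, Smg5 and Decr2, lower, all at adjusted p = 0.996. Vsir, an immune checkpoint receptor, was 102 ± 9.90 and 121 ± 8.81 (SD, n = 3) in the isolated and 96.1 ± 13.9 and 130.5 ± 10.8 in the enriched groups. Arc (-0.105, SE 0.093), Bdnf (0.014, SE 0.062), Npy (-0.043, SE 0.061), Gfap (0.19, SE 0.094), Aif1 (0.17, SE 0.10), Ttr (-0.103, SE 0.66) and Mbp (0.042, SE 0.059) did not pass. Without filtering, 0 probe sets were called for this mean effect.

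None of the other lists was called in any contrast. For the mean effects of KA and of housing, the mean log2 values were 0.051 and -0.011 for astrocyte markers, 0.043 and 0.017 for cytokine and NF-kappaB signalling, 0.015 and 0.038 for oligodendrocyte and myelin genes, -0.038 and 0.0080 for GABAergic interneuron markers, -0.067 and 0.028 for GABA receptor subunits, and 0.0080 and 0.0060 for glutamate receptor subunits. They were 0.0080 and -0.015 for synaptic vesicle genes, -0.025 and -0.022 for postsynaptic and plasticity genes, 0.0080 and 0.029 for neurotrophic and growth factors, 0.046 and -0.0060 for neurogenesis and proliferation, 0.0070 and 0.021 for apoptosis, and 0.027 and -0.035 for oxidative phosphorylation. They were 0.0010 and -0.014 for neuropeptides, 0.052 and 0.029 for glucocorticoid-responsive genes, -0.018 and -0.0010 for cholesterol synthesis, 0.074 and 0.063 for dentate granule cell markers, and -0.016 and 0.039 for pyramidal cell markers. Endothelial and mural cell markers had -0.015 and 0.020, and blood cell markers -0.067 and 0.073. GABA receptor subunits, singled out after their values were seen, had an SE between samples of 0.016 for KA, with 5 of 8 members lower (camera, adjusted p = 0.297, adjusted p = 0.449 with an estimated correlation). Their score was lower in every KA sample than in every PBS sample within each housing (exact permutation p = 0.005, the smallest it can give, or 0.13 adjusted over the lists), but with equal medians the enriched samples overlapped.

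**Figure D4:**
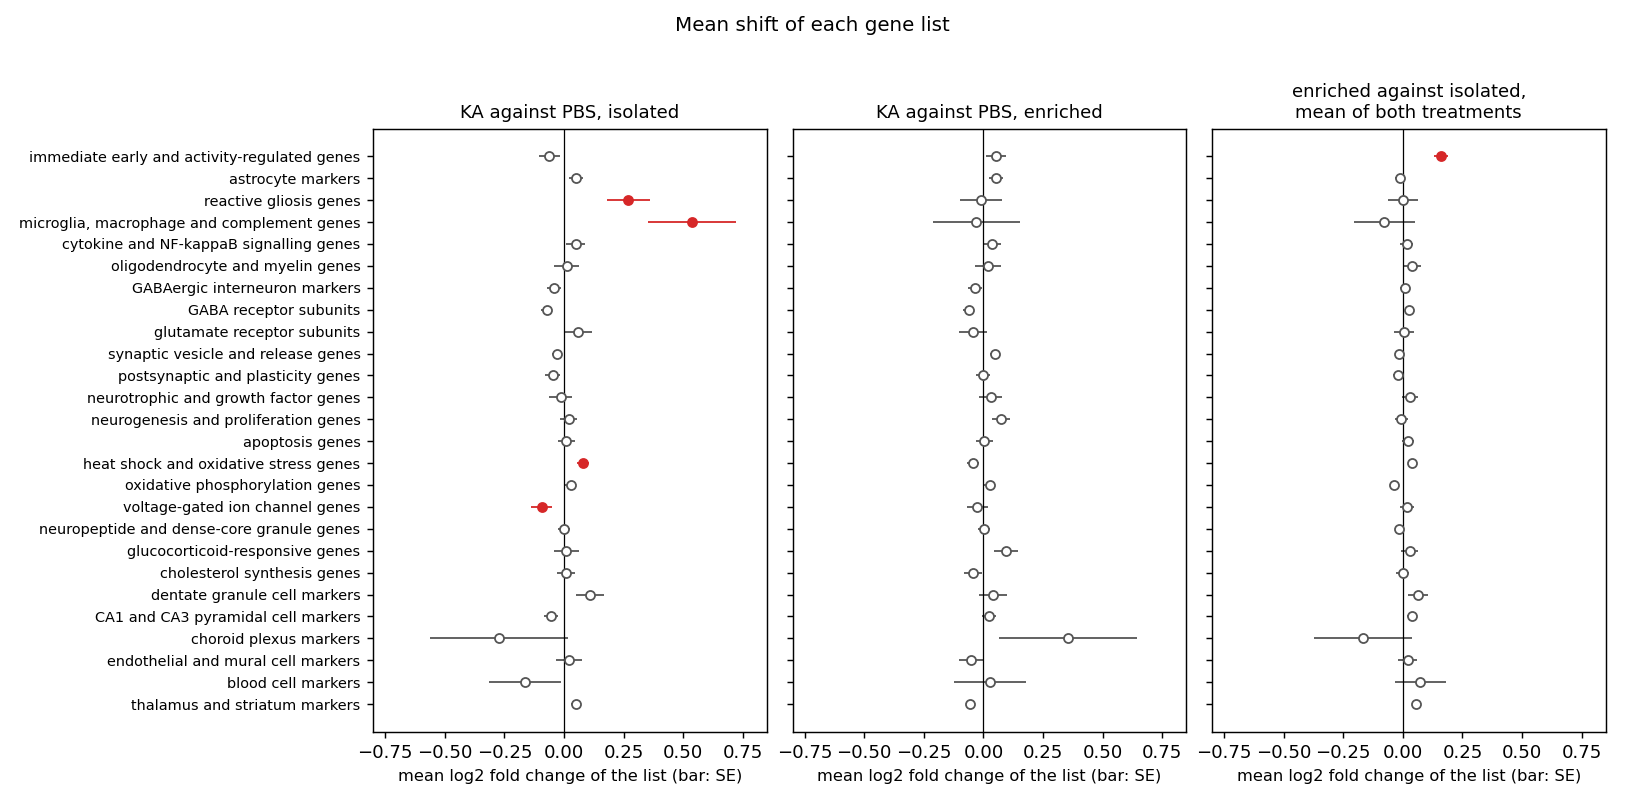
Mean log2 fold change of each of 26 gene lists in 3 contrasts, with the SE between samples as bars; filled red points were called by camera at the preset correlation, and none of them at the estimated one. The microglial list lay at 0.54 in isolated and at -0.03 in enriched rats for KA, and immediate early genes at 0.16 for housing.

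Across all 9520 probe sets the KA effects in the 2 housings correlated near 0 (Pearson r = -0.042, Spearman rho = -0.041), and so did the housing effects in the 2 treatments (0.036 and 0.043). Simulated Pearson values with no effect ran from -0.054 to 0.062 and from -0.038 to 0.041. Most changes were small beside their errors, with a median absolute log2 of 0.065 to 0.078 and a median SE of 0.099. A shared effect is therefore not excluded. No samples are shared in these 2 pairs of contrasts, and probe sets are not independent replicates. Contrasts that share a group correlate by construction. The KA effect in isolated rats and the housing effect in PBS rats, which share PBS_isolated, had r = 0.490 against simulated values of 0.454 to 0.541 with no effect (covariance 0.00687 against 0.00755). The KA effect in isolated rats and the housing effect in KA rats, which share KA_isolated with opposite sign, had -0.501 against -0.530 to -0.458 (covariance -0.00801 against -0.00752). For the KA effect in enriched rats the values were -0.441 against -0.530 to -0.452 with the housing effect in PBS rats (covariance -0.00636 against -0.00752), and 0.569 against 0.463 to 0.536 with the housing effect in KA rats (covariance 0.00935 against 0.00750). These last 2 lie outside the simulated range. The draws treated probe sets as independent and gave all 4 groups the same spread, while KA_enriched replicate 3 stood apart from the other arrays. Groups of 3 samples are too small to be divided. Such draws cannot tell an effect from an unequal spread in a shared group, so no effect is read from these 2 values.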

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

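The tests of mislabelling and of blood below were chosen after the result was seen; the interaction and the other splits of the samples were planned. For the KA effect in enriched minus isolated rats, microglial genes had an interaction of -0.566 (SE between samples 0.258; camera, adjusted p = 6.23e-11, adjusted p = 0.368 with an estimated correlation; exact permutation p = 0.07, or 0.364 adjusted over the lists). Reactive gliosis genes had -0.279 (SE between samples 0.125; adjusted p = 0.00175, adjusted p = 0.368 with an estimated correlation). Heat shock genes had -0.122 (SE between samples 0.037; adjusted p = 0.0454, adjusted p = 0.368 with an estimated correlation). Choroid plexus markers had 0.628 (SE between samples 0.41; adjusted p = 0.0454, adjusted p = 0.436 with an estimated correlation). Each stands here because the difference between the housings was itself tested and called at the preset correlation. Of 100 splits used for the interaction, the real one included, 4 called at least 4 lists, the highest of the others also being 4. This share of 0.04 is not adjusted for the counts of the other contrasts, and with an estimated correlation 0 lists were called. Chance is therefore not excluded for a count of 4. The heat shock and choroid plexus calls were each lost without any 1 of 7 samples, with no filter and with the replicate number as a block. A count of 2 was reached by 34 of the 100 splits, so for a count of 2 chance is not excluded either. The count of probe sets was 0 (limma, 473 at an unadjusted p under 0.05), with up to 2 in the other splits and all 100 at least as high, so there chance is not excluded. Groups of 3 were not tested for outlying samples.

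The microglial pattern is a high state in all 3 KA_isolated samples, in PBS_enriched replicate 2 and in KA_enriched replicate 3, and a low state in the other 7. On immediate early genes alone, the tables argue against PBS_enriched replicate 2 being a KA_isolated sample with a wrong label. Its score was 0.156 and the highest isolated score was 0.056. That list was picked after its housing difference was seen, with this sample counted as enriched, but its mean housing call held without each sample in turn. The sample's reactive gliosis score of 0.311 lay within the KA_isolated range of 0.167 to 0.384. Its thalamus and striatum score of 0.115 lay above the KA_isolated range of 0.024 to 0.068. Blood left in the tissue is argued against, since blood cell markers had a log2 of -0.163 (SE between samples 0.151) in KA_isolated against PBS_isolated. An exchange of PBS_enriched replicate 2 with a KA_enriched sample stays open, since 0 probe sets were called between KA and PBS in enriched rats (limma, 474 at an unadjusted p under 0.05). The 3 lists whose scores separated these groups cannot decide it, since separation by label put the sample on its labelled side in advance. It lay outside the KA_enriched range by no more than the SE between samples: GABA receptors (-0.006 there, -0.067 to -0.018 in KA_enriched, SE 0.023), choroid plexus (-0.426, -0.328 to 0.142, SE 0.290) and thalamus and striatum (0.115, 0.019 to 0.096, SE 0.019). The first and last overlapped with equal medians, and the last also with quantile normalization. A response to KA that enrichment lessens, or isolation raises, in some pools may also account for the interaction. Such a response leaves the high PBS_enriched pool without a reason and was not tested separately. Without PBS_enriched replicate 2 the interaction was -0.393, and without KA_enriched replicate 3 it was -0.738.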

How the results depend on the processing

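The beta-actin covariate was chosen after the data were seen; the other alternatives were planned. Correlations between contrasts kept their side in all 24 comparisons with alternatives. Those with the replicate block were fixed in advance, since the block is balanced over the groups and cannot change a log2 fold change. Correlations with a sample left out are not among the 24. Of 202 gene results 16 changed sign under at least 1 alternative. The fit of only the groups compared gives no value for the interaction and the mean effects, and 1 probe set per gene gives none for single genes. Where a value below differs from the main one, the cause was not tested. When a sample is left out, its group keeps 2 and shares the spread of the other groups. Dim genes near the background limit what these arrays can show.

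With an estimated correlation 0 lists were called in any contrast, with the same means. For KA in isolated rats the microglial list had 0.536 (adjusted p = 0.135), reactive gliosis 0.27 (0.135), heat shock 0.0788 (0.267) and ion channels -0.0938 (0.306). For housing in PBS rats immediate early genes had 0.103 (0.327), reactive gliosis 0.141 (0.516), microglia 0.206 (0.623), heat shock 0.0992 (0.299), choroid plexus -0.482 (0.458) and thalamus and striatum 0.107 (0.299). For housing in KA rats immediate early genes had 0.219 (0.0945), reactive gliosis -0.138 (0.611) and microglia -0.359 (0.611). For the interaction reactive gliosis had -0.279, microglia -0.566 and heat shock -0.122 (all 0.368), and choroid plexus 0.628 (0.436). For the mean KA effect reactive gliosis had 0.131 and microglia 0.253 (both 0.449), and for the mean housing effect immediate early genes had 0.161 (0.0707). With fry the same lists lost their calls at these means, except thalamus and striatum for housing in PBS rats (adjusted p = 0.0181) and immediate early genes for housing in KA rats (0.0172) and for the mean housing effect (0.0104), so fry called 0 lists for KA in isolated rats, the interaction and the mean KA effect, and 1 for each of the 3 housing contrasts.

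With quantile normalization the heat shock list for KA in isolated rats had 0.0755 and reactive gliosis for housing in PBS rats 0.129, both no longer called. With equal medians reactive gliosis for housing in KA rats had -0.157, no longer called, and 1 probe set was called for the mean housing effect. With no filter heat shock for KA in isolated rats had 0.0721, reactive gliosis and choroid plexus for housing in PBS rats 0.0803 and -0.129, and heat shock and choroid plexus for the interaction -0.101 and 0.241, all no longer called, leaving 2 lists for the interaction; for the mean KA effect 0 probe sets were called (limma, lowest adjusted p = 0.0553, 714 at an unadjusted p under 0.05). With a lower pseudocount 1 probe set was called for the mean housing effect, and with array weights 1. For housing in PBS rats 2 probe sets were called with a stricter filter and 2 with array weights. With only the groups compared 5 were called for KA in isolated rats. With the covariate heat shock for KA in isolated rats had 0.0787, and for housing in PBS rats reactive gliosis 0.126, choroid plexus -0.398 and thalamus and striatum 0.0957, all no longer called, leaving 3 lists there; the mean housing effect then had 1 probe set and 3 lists.

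Same-number samples of different groups had residual correlations from -0.072 to 0.199, with a mean of 0.050 and 2 of 18 over 0.1. Different-number samples had -0.142 to 0.101, with a mean of -0.025 and 1 of 36 over 0.1. With the block, more probe sets had an unadjusted p under 0.05 in every contrast (limma), such as 612 against 537 for the mean housing effect. The numbers were not read as pairs, but an effect shared by samples of the same number is not excluded. With the replicate number as a block the mean housing effect had 1 probe set, and the interaction 2 lists, heat shock (-0.122) and choroid plexus (0.628) being no longer called (both adjusted p = 0.0507); it changed no other call of probe sets or lists.

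Signs that turned were all of genes that did not pass. Gfap for KA in enriched rats was -0.0201 with array weights, Gfap for housing in PBS rats 0.0124 with quantile normalization, Mbp for the mean KA effect -0.0168 with quantile normalization, Mbp for the mean housing effect -0.0027 with equal medians, Bdnf for the mean KA effect -0.0142 with array weights, and Ttr for the mean KA effect 0.148 with the covariate. With each sample left out in turn, values ran as follows. For KA in isolated rats Aif1 ran from -0.159 to 0.144, Npy from -0.0944 to 0.00387, Ttr from -2.11 to 0.248 and Mbp from -0.0962 to 0.034. For KA in enriched rats Gfap ran from -0.0445 to 0.176 and Arc from -0.0206 to 0.279. For housing in PBS rats Gfap ran from -0.11 to 0.0731, Aif1 from -0.292 to 0.0114 and Mbp from -0.0942 to 0.00307. For housing in KA rats Ttr ran from -0.467 to 0.782, and for the interaction Npy from -0.0955 to 0.0404. For the mean KA effect Bdnf ran from -0.0191 to 0.0511 and Ttr from -0.611 to 0.567, and for the mean housing effect Aif1 from -0.0604 to 0.0912 and Mbp from -0.017 to 0.0481.

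Lists with each sample left out ran, for KA in isolated rats, from 0.0684 to 0.0984 for heat shock and from -0.114 to -0.059 for ion channels, with 2 to 5 lists called. For KA in enriched rats 0 to 1 lists were called. For housing in PBS rats immediate early genes ran from 0.0736 to 0.137, reactive gliosis from 0.0556 to 0.195, microglia from 0.0338 to 0.3, heat shock from 0.0845 to 0.119, choroid plexus from -0.733 to -0.124 and thalamus and striatum from 0.101 to 0.111, with 1 to 2 probe sets and 1 to 7 lists called. For housing in KA rats reactive gliosis ran from -0.189 to -0.081, with 0 to 1 probe sets called. For the interaction heat shock ran from -0.141 to -0.0964 and choroid plexus from 0.27 to 0.879, with 2 to 5 lists called. For the mean KA effect 2 to 5 lists were called, and for the mean housing effect 1 to 2 probe sets and 1 to 4 lists.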

Other observations

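Of the tests below, the covariate for RNA quality and its prediction came before its result was seen, though the covariate was added after the data were examined, and the splits were planned; the others were chosen after the result was seen. Per1, a clock gene that activity and glucocorticoids also induce, had low signals in 3 samples: 30.43 in PBS_isolated replicate 3, and 26.47 and 19.22 in PBS_enriched replicates 1 and 3. In the other 9 samples it lay between 57.5 and 85.91. Per1 was singled out after its values were seen, and its differences between groups did not pass.

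Immediate early genes were higher in enriched rats by a mean log2 of 0.161, and a response of these genes to the enriched cage may be a reason. The tables argue against a single sample as the source, since the lowest mean with any sample left out was 0.144. Thalamus or striatum in the dissection is argued against in KA rats, where their markers had a log2 of 0.002 (SE between samples 0.019) and immediate early genes 0.219. It stays open in PBS rats, where the markers were higher by 0.107 (SE between samples 0.019) and immediate early genes by 0.103. No list held markers of neocortex, so that tissue was not tested. The tables argue against RNA quality as the whole source, since with the beta-actin covariate the list had 0.172 (SE 0.037, from 0.161 with SE 0.030); Egr1 went from 0.454 (SE 0.065) to 0.436 (SE 0.077), with 1 residual degree of freedom fewer, and its call ended; which of these ended it was not tested. A larger housing effect after KA than after PBS stays open, with an interaction of 0.116 (SE between samples 0.060, exact permutation p = 0.365), as do handling or cage before tissue was taken, which go with the housing groups and were not tested.

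Anp32a was high in the 3 PBS_isolated samples only. A batch shared by these 3 arrays is argued against as a broad effect, since 68 probe sets set PBS_isolated apart from the other 9 samples, against 86.5 by chance and 115, 80 and 92 for KA_isolated, PBS_enriched and KA_enriched. A fault of 1 probe set stays open, since the array holds 0 other tested probe sets of the gene. That KA and enrichment each lower Anp32a is a hypothesis these samples cannot settle. Nor can they tell a fall with enrichment from a rise with isolation.

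The other splits of the samples bear on the counts. With 10 splits of 3 against 3 the splits are too few for a share under 0.05. For KA in isolated rats the real counts were 1 probe set and 4 lists, reached by 1 split each, the highest others being 0 and 2. For KA in enriched rats they were 0 and 0 (limma, 474 at an unadjusted p under 0.05), reached by all 10 splits, the highest others being 0 and 3. For housing in PBS rats they were 1 and 6, reached by 3 splits and 1 split, the highest others being 1 and 4. For housing in KA rats they were 0 (limma, 668 at an unadjusted p under 0.05) and 3, reached by 10 splits and 1 split, the highest others being 1 and 2. With 100 splits, the real one included, the 2 probe sets of the mean housing effect were reached by 3 splits, with a highest other of 2. That share is under 0.05 but is not adjusted for the counts of the other contrasts, so chance is not excluded. Without Egr1, whose call is lost when any sample is left out, the count is 1, which 8 splits reached, so for a count of 1 chance is not excluded; this does not test Anp32a itself. Nor is it excluded for the 1 list of that effect, reached by 62 with a highest other of 4. It is not excluded for the mean KA effect, with 1 probe set reached by 6 splits (highest other 2) and 2 lists reached by 34 (highest other 6).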
